A study of Brassica rapa with 5 samples.

How the data were processed

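Digital gene expression libraries, in which short sequence tags are counted per gene, were made from leaf RNA of Brassica rapa accession R-o-18 grown in hydroponics. Per the labels' protocols, plants grew for 14 days in a normal nutrient solution with 2 µM Zn, 3 µM Fe and no Cd, and were then kept in it or moved for 7 days to 0.05 µM Fe, 0.005 µM Zn, 50 µM Zn or 1 µM Cd. The first pair of expanded leaves was harvested. Per the labels, each condition had 3 replicates of 3 plants each, and the series' design text counts 15 libraries. The deposited data are 1 table per condition, so 5 tables were analysed. Each condition is therefore 1 sample with the values of 3 libraries averaged in it.

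Per the file headers, each table lists a gene identifier, the number of clean tags and the TPM. The deposited tag numbers are estimated counts, not whole. Between 76.9% and 78.4% of them were multiples of 1 tag divided by 3 (within 0.0001 tag, and a proportionally wider margin above 10 tags), as a mean of 3 libraries gives. The others were smaller fractions, the form that tags divided among several matching genes would take. The deposited TPM values, tags per 1000000 clean tags, summed to between 540253 (Cd exposure) and 585704 (Fe deficiency) per condition, so 54.0% to 58.6% of clean tags were assigned to genes. The mean number of tags in genes ranged from 3114182 (Cd exposure) to 3435599 (Fe deficiency) per condition. The mapping tool, genome build and gene annotation are not given in the sources used here. A gene missing from a table was taken as 0 tags in that condition. The smallest listed value was 0.0108 tag.

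The 2 deposited columns weight the 3 libraries of a condition differently, and this was used to recover what they hold of the replicates. Among genes with 0.333 tag, which have 1 tag in 1 library, the TPM took 3 common values per condition, and these covered 85.3% to 95.2% of such genes. They give the clean-tag totals of the 3 libraries, which ranged from 5575674 to 5997199 over all conditions. As a check, genes with a whole sum of up to 12 tags were solved for whole tags in the 3 libraries. Both columns had a solution for 93.9% to 95.4% of them, against at most 0.94% when the totals were moved by 0.5%. For every gene, the tag mean minus the TPM times the mean library total is then a weighted difference between the 3 libraries that is 0 when they agree. It gives 1 estimate of the spread between libraries per gene and condition, referred to below as the library contrast. In genes whose tags in each library could be solved (sums of 10 to 40 tags), the spread from this contrast was 0.91 to 1.08 times the spread of the solved tags. At 0.057 to 0.058 TPM per tag over a condition, such sums lie below 5 TPM, the minimum mean of the genes tested below. Counting error is large there (coefficient of variation 0.51 to 0.63 from solved tags), so the contrast was not checked in this way at the levels tested. A library weighs in the contrast by the distance of its total from the mean total. The library with the middle total had 60.8% of the weight of the one with the highest total in the control and 75.2% in Fe deficiency, but 2.54% in Zn deficiency, 7.52% in Zn excess and 1.56% in Cd exposure, so in these 3 conditions a deviation of the middle library is largely missed. In Zn excess the totals differed by only 0.84%, against 5.31% in the control.

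All values were TPM as the authors normalised them. Changes are log2 of (TPM + 1) in a condition minus the same in the control, which understates the change of genes with low TPM. Genes with a mean over the 5 conditions of at least 5 TPM were kept, 10807 of the 29183 genes listed in any table. A gene was called higher or lower when this value changed at least 2-fold. No test was planned for tables with 1 value per condition, so these counts are counts by size. As an addition made after the tables were seen, the library contrasts were turned into a test. The squared contrasts were scaled by their trend on expression in each condition, averaged over the 5 conditions (5 degrees of freedom) and moderated across genes with limma 3.58.1 in R 4.3.3 (12.0 degrees of freedom in all). The spread of a gene that varies more in 1 condition than in the others is therefore understated there. The adjusted p-values below come from this test with Benjamini-Hochberg adjustment, and the standard errors (SE) from the same fit. Each replicate pooled 3 plants per the labels, so the spread is that between replicate pools.

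The test was run on simulated libraries with known totals and spread. With 94 genes changed 2-fold and 101 changed 4-fold among 10801 in the simulated Fe deficiency comparison, 78.7% and 100% were recovered, and 11 unchanged genes were called. In the simulated comparisons with no changed gene no gene was called, and 4.84% (Cd exposure) to 5.74% (Zn excess) of genes had an unadjusted p under 0.05. The simulation gave all genes of a condition the same relative spread, drawn independently for each gene. It does not cover genes that vary together or in some conditions only, so the real error rate may be higher.

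The 4 comparisons share the control. For each of the 6 pairs, 100 sets of unchanged conditions were simulated with the recovered spread and a shared control, and the overlap expected of independent lists was computed from the 2 numbers of calls. The simulated error of each gene was drawn independently of the other genes. The alternatives were pseudocounts of 0.1 and 5, no filter or a minimum mean of 20 TPM, scaling by median-of-ratios size factors, and a 4-fold threshold. Genes with tag values that were multiples of 1 tag divided by 3 in every table, and the adjusted p, were added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

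The tables give identifiers without gene names. None of the 29183 identifiers matched the RefSeq gene table used here for names, so no gene could be named or placed on a chromosome. The 16 lists of 296 Arabidopsis loci that had been fixed before the data were examined (iron and zinc transport, photosynthesis and others) could not be applied and were not analysed. The rule fixed for this case was to report the 2 identifiers with the largest change in each direction of each comparison.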

Results

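Transcript levels were measured in leaves of Brassica rapa, a Brassicaceae crop species, under 4 disturbances of trace metal supply and under normal supply. Fe and Zn are essential cofactors for plants, whereas Cd is a toxic metal without a known role in this species. The deposited values were means of 3 libraries per condition. Each condition had 25439 (Cd exposure) to 26284 (Zn deficiency) genes with at least part of a tag, and libraries held on average 5744074 (Zn deficiency) to 5867647 (Fe deficiency) clean tags. For a gene at 5 to 30 TPM, the spread between libraries recovered from the 2 columns corresponded to a coefficient of variation of 20.9% in Cd exposure, 21.2% in the control, 24.5% in Fe deficiency, 31.0% in Zn excess and 40.2% in Zn deficiency. Counting error alone would give 12.1% to 13.7%. The question asked of each comparison was which genes respond to the condition, and a further set of comparisons asked which responses are shared.

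Fe deficiency gave the most genes changed at least 2-fold. Of 10807 genes, 402 were at least 2-fold higher and 139 at least 2-fold lower than in the control. Of these, 379 rose and 129 fell at an adjusted p under 0.05 (limma on the recovered spread). The gene with the largest rise was Bra005795, from 2.17 to 536 TPM, 247-fold, with a log2 change of 7.40 (SE 0.42) and an adjusted p of 1.05e-06. Some of its tags were fractions, so they may be shared with a similar gene. Bra004609 had no tag in the control and 98.8 TPM under Fe deficiency, at least 576-fold higher when the control is set to a floor of 3 tags over its 3 libraries (0.172 TPM; adjusted p 6.30e-05). With a pseudocount of 0.1 its log2 change was the larger, 9.95 against 7.88 for Bra005795. The largest falls on the (TPM + 1) scale were in 2 genes that were abundant in the control. As a plain TPM ratio, Bra028271 fell further, from 51.3 to 1.34 TPM. Bra031471, which also had fractional tags, fell from 1231 to 43.5 TPM, 28.3-fold (log2 change -4.79, SE 0.28, adjusted p 1.23e-06). Bra013863 fell from 1255 to 52.2 TPM, 24.0-fold (log2 change -4.56, SE 0.20, adjusted p 2.67e-07).

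The predominance of higher genes under Fe deficiency depended on scaling. The median gene was 0.17 higher on the log2 scale. A larger share of clean tags lay in genes (58.6% against 57.2% in the control), a difference too small to give the whole shift. With median-of-ratios size factors, which remove a shift of 0.18, 267 genes were higher and 201 lower, so the share of higher genes among the changed ones was 57.1% in place of 74.3%.

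Zn excess changed fewer genes, 96 at least 2-fold higher and 120 at least 2-fold lower. Of these, 62 rose and 66 fell at an adjusted p under 0.05. Its largest changes were in genes that had also stood out under Fe deficiency. Bra004609 reached 114 TPM, at least 665-fold above the floor of the control (adjusted p 0.000292), and Bra005795 reached 358 TPM, 165-fold above the control (log2 change 6.82, SE 0.50, adjusted p 2.42e-05). Bra028271 fell from 51.3 to 2.07 TPM, 24.8-fold (log2 change -4.09, SE 0.29, adjusted p 1.97e-05), and Bra031471 fell to 75.1 TPM, 16.4-fold (log2 change -4.02, SE 0.35, adjusted p 0.000106). Bra028271 stood at 1.34 TPM and Bra013863 at 52.2 TPM under Fe deficiency, against 2.07 and 183 TPM under Zn excess.

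Under Cd exposure the changed genes were mostly lower. At least 2-fold higher values were found for 25 genes and at least 2-fold lower values for 316, and 25 rose and 276 fell at an adjusted p under 0.05. The balance was less one-sided without the size threshold: 311 genes rose and 775 fell at an adjusted p under 0.05 whatever their fold change, 1086 in all, against 807 and 216 (1023) under Fe deficiency. The test used TPM without size factors. A general shift (median log2 change -0.073 under Cd exposure and 0.17 under Fe deficiency) therefore enters these counts and their balance. The largest changes were smaller than those under Fe deficiency or Zn excess, and no rise reached 4-fold on this scale. Bra034674, which had fractional tags, rose from 21.3 to 76.6 TPM (3.59-fold, log2 change 1.80, SE 0.25, adjusted p 0.00295), and Bra009188 rose from 4.1 to 12.6 TPM (3.08-fold, log2 change 1.42, SE 0.30, adjusted p 0.0157). Bra021110 fell from 26.1 to 2.08 TPM, 12.5-fold (log2 change -3.14, SE 0.65, adjusted p 0.0144), and Bra019002 fell from 39.4 to 3.87 TPM, 10.2-fold (log2 change -3.05, SE 0.50, adjusted p 0.00551). The share of clean tags in genes was lowest here, 54.0%. With median-of-ratios size factors, which remove a shift of -0.12, 60 genes were higher and 223 lower, and the share of higher genes was 21.2% in place of 7.33%.

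Zn deficiency gave 288 genes at least 2-fold higher and 65 at least 2-fold lower, but the spread between its libraries was the widest of the 5 conditions and only 3 of these changes passed the test (limma, adjusted p under 0.05). The median SE of a log2 change was 0.30, against 0.21 under Fe deficiency and 0.19 under Cd exposure. At an unadjusted p under 0.05 (limma), 334 of the 353 changes passed. These were chosen by size, and at this SE nearly all such changes pass. Of all 10807 genes, 1074 had an unadjusted p under 0.05. Bra039194 rose from 0.414 to 109 TPM (7 tags over the 3 control libraries and 1933 under Zn deficiency), 265-fold, with a log2 change of 6.29 (SE 0.79, adjusted p 0.0173). Its level in the other 3 treatments was 0.460 to 0.751 TPM. Bra027108, with fractional tags, rose from 0.941 to 22.2 TPM, 23.6-fold (log2 change 3.58, SE 0.40, adjusted p 0.0125). Bra035742 fell from 43.5 to 7.97 TPM, 5.46-fold (log2 change -2.31, SE 0.30, adjusted p 0.0173), and stood at 11.7 TPM under Zn excess, 118 TPM under Fe deficiency and 117 TPM under Cd exposure. Bra021856, the next in size, was at 18.4 TPM in the control and 5.23 TPM under Zn deficiency, with an adjusted p of 0.218.

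**Figure D1:**
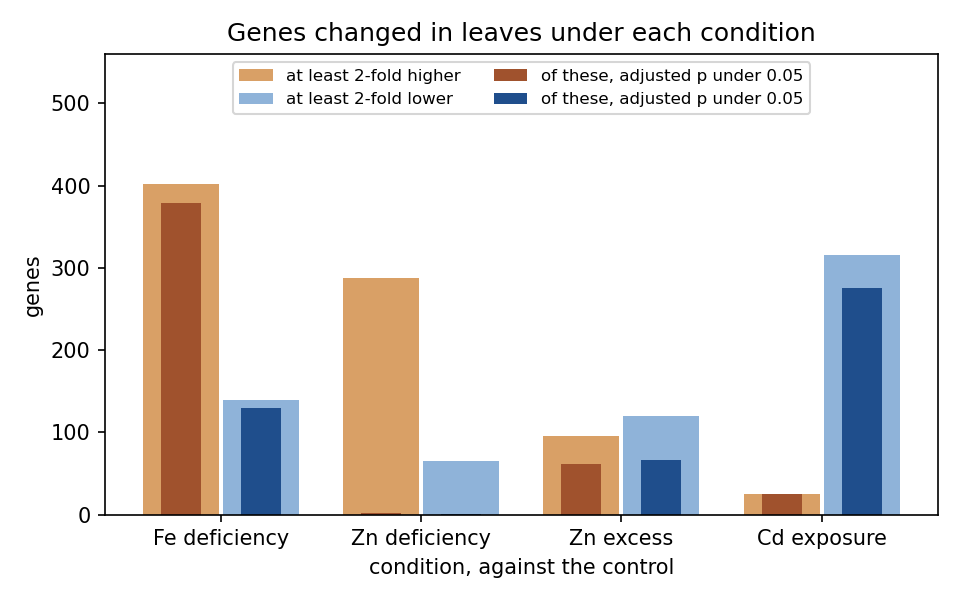
Number of genes (vertical axis) at least 2-fold higher or lower than the control on the (TPM + 1) scale in each condition (wide bars), and those among them with an adjusted p under 0.05 from the recovered spread (narrow bars). Under Fe deficiency 379 of 402 higher genes passed the test, under Zn deficiency 2 of 288.

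The conditions were then compared for shared changes. Fe deficiency and Zn excess shared 105 genes changed the same way, 44 higher and 61 lower in both. Independent lists would share 5.11 and unchanged conditions with the same control 1.13. Of the 105, 79 passed the test in both conditions, 31 higher and 48 lower. This number may be too high. The test averages the spread of a gene over the 5 conditions, and these genes varied between libraries mainly within Fe deficiency and Zn excess. The 44 genes had a median log2 change of 2.44 under Fe deficiency and 1.86 under Zn excess, and the 61 genes of -1.89 and -1.67. Across all genes tested, which are not independent replicates, the changes correlated with r = 0.47 (Spearman's rho 0.32), against 0.33 for simulated unchanged conditions. Their covariance was 0.098 against 0.021 simulated. Part of the excess in overlap may come from the shared control, which is 1 table and could not be split.

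**Figure D2:**
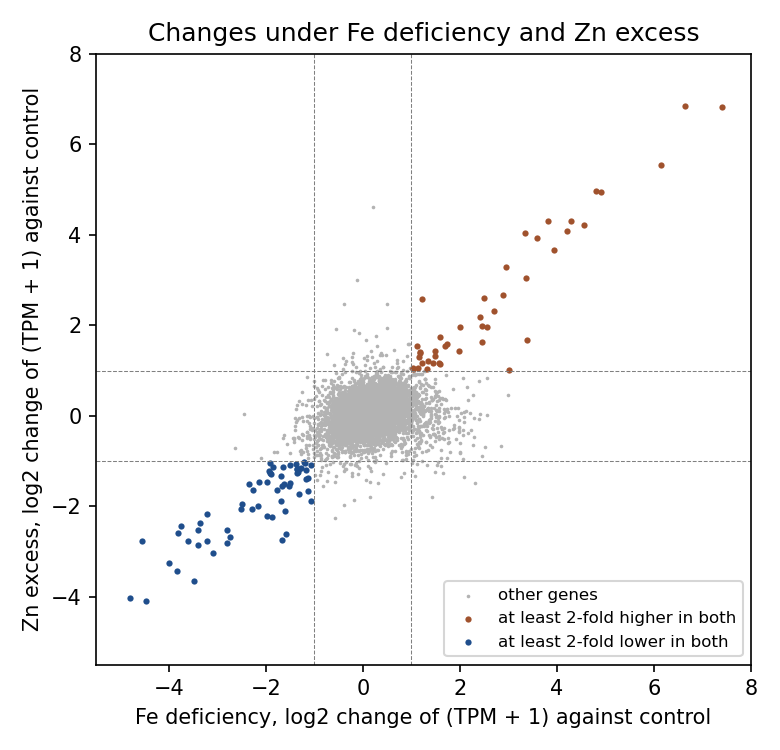
Log2 change of (TPM + 1) against the control under Fe deficiency (horizontal axis) and Zn excess (vertical axis), 1 point per gene for the 10807 genes tested, with dashed lines at 2-fold. The 44 genes higher and 61 genes lower in both conditions run along the diagonal away from the cloud of other genes.

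Zn deficiency and Zn excess moved the same nutrient in opposite directions, and 13 genes changed in opposite ways under them while 21 changed the same way. Independent lists would give 3.78 and 3.28, and simulated unchanged conditions with a shared control 0.29 and 2.32. Across all genes r was 0.204, against 0.232 for a shared control alone. It also depends on how widely each change varies, so it is not a like measure in real and simulated conditions. The covariance was 0.0386, against 0.0208 simulated (SD 0.00099). The simulation drew the error of each gene independently, so such an SD is too small where genes vary together between libraries. None of the 13 passed the test in both conditions, and 11 did at an unadjusted p under 0.05. Genes chosen by size mostly pass at an unadjusted p, so such numbers say little, here and for the pairs below. Fe deficiency and Zn deficiency shared 104 genes, against 11.5 for independent lists and 1.23 for simulated unchanged conditions. Across all genes their r was 0.309, against 0.278 for a shared control alone. Their covariance was 0.0716, against 0.0208 simulated (SD 0.00068). With no library in common, r was -0.095 when the Zn deficiency change was taken against Zn excess and 0.221 when taken against Cd exposure. The first value shows only which Zn condition resembled Fe deficiency more, so it cannot tell whether the control is the source. With its sign turned, it is the same quantity as the value given below for Fe deficiency and Zn excess. None of the 104 passed the test in both (limma, adjusted p), and 95 did at an unadjusted p under 0.05. The overlaps of Cd exposure with the 2 deficiencies ran the other way. Of the 316 genes lower there, 74 were higher under Fe deficiency and 62 were higher under Zn deficiency, against 11.8 and 8.42 for independent lists. In the comparison with Fe deficiency, 58 of the 75 genes changed in opposite ways passed the test in both, and in the comparison with Zn deficiency 1 of 65 did (60 at an unadjusted p under 0.05). The 58 may be too many, since the test averages the spread of a gene over the 5 conditions. Of the 75, 36 were higher under both deficiencies, lower under Cd exposure and past the threshold in neither direction under Zn excess. They belong to the 62 genes, which varied widely between control libraries (median library contrast -51.0%, central 95% of random lists -4.61% to 6.25%). No gene changed the same way under Zn deficiency and Cd exposure, where independent lists would share 2.57, and r was -0.25 where a shared control alone gave 0.30. Fe deficiency and Cd exposure shared 21 genes changed the same way (4.99 for independent lists and 0.64 for simulated unchanged conditions), but across all genes r was -0.031 where a shared control alone gave 0.436. Zn excess and Cd exposure shared 19 (3.73 and 0.9), with 11 changed in opposite ways (3.08 for independent lists). Their r was 0.121 against 0.365 for a shared control alone, and the covariance of 0.0213 lay within 1 SD of that expected of the shared control (0.0208, SD 0.00068).

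**Figure D3:**
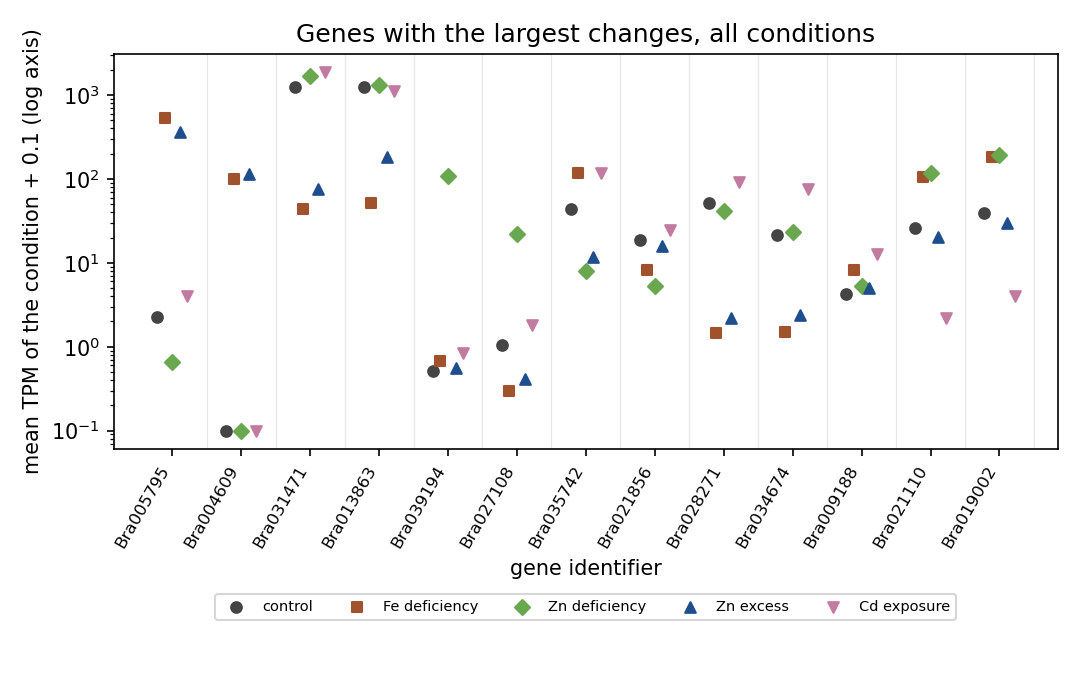
Mean TPM plus 0.1 (vertical log axis) of the 13 genes with the largest changes in each comparison, 1 symbol per condition. Bra005795 and Bra004609 lie at 98.8 to 536 TPM in Fe deficiency and Zn excess and at 3.93 TPM or less in the other conditions.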

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

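The counts of changed genes moved with the settings, as counts by size do, and 53 of 120 counts under alternatives stayed within 1.5 times the reported one. Counts are given in the order Fe deficiency, Zn deficiency, Zn excess and Cd exposure. With a pseudocount of 5, 245, 128, 62 and 12 genes were higher and 81, 21, 70 and 128 lower. The counts of shared genes were then 49 for Fe and Zn deficiency, 10 for Zn deficiency and Zn excess and 8 for Zn excess and Cd exposure, and 4 genes changed in opposite ways under the 2 Zn conditions. With a pseudocount of 0.1, 112 genes were lower under Zn deficiency and 49 higher under Cd exposure. Cd exposure then shared 35 genes with Fe deficiency, 2 with Zn deficiency and 32 with Zn excess, and 22 genes changed in opposite ways under the 2 Zn conditions. Without a filter on low values, 657, 448, 202 and 61 genes were higher, and 1 was shared by Zn deficiency and Cd exposure. With a minimum mean of 20 TPM, which tests fewer genes, 175, 126, 38 and 12 were higher and 68, 28, 70 and 157 lower. The shared counts were then 51 for Fe and Zn deficiency, 58 for Fe deficiency and Zn excess, 12 for both Zn conditions and 10 for Zn excess and Cd exposure, with 8 genes opposite under the Zn conditions. At 4-fold, 55, 14, 23 and 0 genes were higher and 28, 1 (Bra035742), 26 and 10 lower. Fe deficiency and Zn excess still shared 38 genes at 4-fold, Fe and Zn deficiency 4, and the other pairs 0, with 2 opposite under the Zn conditions. Size factors gave 267 higher genes under Fe deficiency and 60 under Cd exposure. Among genes with no fractional tags, also a smaller set, 251, 187 and 62 were higher in the first 3 comparisons, 86 were lower under Fe deficiency and 195 under Cd exposure, and Fe deficiency shared 65 genes with Zn excess and 13 with Cd exposure. Requiring the adjusted p as well left 2 higher and 1 lower genes under Zn deficiency and 62 and 66 under Zn excess, and shared counts of 0 for Fe and Zn deficiency, 1 for both Zn conditions and 8 for Zn excess and Cd exposure, with 0 opposite under the Zn conditions. The requirement of an adjusted p and the restriction to genes without fractional tags were chosen after seeing the data. For the other moves the cause was not tested. The correlation across genes between Fe deficiency and Cd exposure changed sign without the filter (0.048 against -0.031). That between Zn deficiency and Cd exposure was -0.097 without the filter and -0.348 with a minimum mean of 20 TPM, against -0.251. The changes of the 13 named genes kept their direction under both other pseudocounts and the size factors, and 30 of their 48 values stayed within 1 SE. No paired analysis was possible because each condition was deposited as 1 mean table, and for the same reason no replicate could be left out, no count model with replicates could be run and no other grouping of the libraries could be tried. No single result met the criteria for an outlying sample, since each condition is 1 sample.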

Other observations

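The gene groups of this part, the tests of the shared control on the 105 genes and by the covariance, of single libraries and of the spread between libraries within the gene groups, and the test of that spread for Zn deficiency were chosen after the data were seen, and the other tests were set before their results were known. Of the genes that changed alike under Fe deficiency and Zn excess, those lower in both held a larger share of falls past the test under Cd exposure than genes in general. The group as a whole was not shifted. All 3 comparisons share the control, which may add to these falls. Of the 61 genes lower in both, 3 rose and 11 fell at an adjusted p under 0.05 (limma on the recovered spread), against 311 and 775 of all 10807 genes. The difference in shares was not tested. The median log2 change of the 61 genes under Cd exposure was -0.00486, with 30 above 0 and 31 below. Of the 44 genes higher in both, 2 rose and 3 fell, near the share among all genes. Bra034674, the gene with the largest rise under Cd exposure (76.6 TPM), stood at 1.41 TPM under Fe deficiency and 2.28 TPM under Zn excess, against 21.3 TPM in the control. Bra028271 was at 90.7 TPM under Cd exposure and 51.3 TPM in the control.

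A second group crossed the conditions. It held the 62 genes higher under Zn deficiency and lower under Cd exposure, among them Bra021110 and Bra019002. Their median log2 change was 1.18 under Fe deficiency, where 57 of 62 lay above 0 and 34 rose at an adjusted p under 0.05, and 0.020 under Zn excess. Under Zn deficiency none passed the adjusted test, and under Cd exposure, where they had been chosen as lower, 56 did. Bra021110 stood at 26.1 TPM in the control, 106 under Fe deficiency, 119 under Zn deficiency, 20.2 under Zn excess and 2.08 under Cd exposure.

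For the 105 genes shared by Fe deficiency and Zn excess, the shared control cannot be the whole source. A control that was off for these genes would move them as far under Zn deficiency and Cd exposure, which are set against the same table. Taken in the direction of the shared change, the median log2 change of the 105 genes was 0.00264 under Zn deficiency (quartiles -0.384 and 0.298) and 0.00486 under Cd exposure (quartiles -0.216 and 0.370), whereas the smaller of each gene's 2 shared changes had a median of 1.59 and a lower quartile of 1.18. In the test set in advance, with no library in common, the Fe deficiency change correlated across all genes with the Zn excess change at r = 0.371 when the latter was taken against Cd exposure and at 0.095 when taken against Zn deficiency. The second value fell just short of the 0.1 set in advance. It compares the 2 Zn conditions in their likeness to Fe deficiency and would fall toward 0 if both resembled it. This test alone therefore does not decide for the correlation across all genes. There the covariance of the changes was 0.098, against 0.021 (SD 0.00066 over 100 simulations) for unchanged conditions with a shared control. The simulation drew the error of each gene independently, so this SD is too small where genes vary together between libraries. The covariance therefore does not exclude the control as the whole source either. Of the 105 genes, 65 had no fractional tags (61.9% against 62.5% of all genes tested, Fisher's exact test, p = 0.919), which argues against tags divided between similar genes.

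The spread between libraries fits as part of this pattern, because the 105 genes varied between libraries within both conditions. The median library contrast of the 44 higher genes was -26.3% of their level within Fe deficiency (central 95% of random lists, -10.5% to 6.32%) and 27.3% within Zn excess (-5.45% to 16.6%), and that of the 61 lower genes was 41.2% (-8.22% to 5.78%) and -14.0% (-5.53% to 13.5%). Within the control, Zn deficiency and Cd exposure the medians of both groups lay inside the range of random lists. A test set in advance, the correlation across all genes given the ranks of the 5 library contrasts (0.505), stayed above the bound set for it. It cannot decide whether the spread is the source of the correlation across all genes. A difference between libraries need not track the error of their mean, which is what would give a false correlation. The test was also taken over a set that dilutes the 105 genes and does not exclude the spread for these. A change in 1 library alone is excluded for part of the pattern. For the 61 lower genes the size of the call already rules out a fall in 1 library alone, since the loss of all tags in 1 of 3 libraries, with the others at the control level, lowers the mean by less than 2-fold. Of these genes, 31 stood at less than the control level divided by 3 in both conditions, so each of the 3 libraries of each condition was below the control mean. A rise of the 44 genes in 1 library of Fe deficiency would have given a library contrast of at least 86.9% in size, against quartiles of -43.4% and -10.5%. This holds for the genes as a group and for a rise in 1 library alone. It does not cover each gene, or a rise that was only stronger in 1 library. For Zn excess a rise in 1 library alone cannot be told apart, since in the library with the middle total it would give only 11.7%. A response to the conditions that differed in strength between replicates and variation of these genes for another reason both stay open. A response of leaves to low Fe under both conditions remains a hypothesis, since leaf Fe was not measured in these tables and no gene could be named.

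The many genes changed by size under Zn deficiency may reflect differences between single libraries or plants more than the Zn supply. The library contrast within Zn excess, which uses no Zn deficiency or control library, correlated with the Zn deficiency change across genes (Spearman's rho 0.480; the largest of 1000 random orders of genes reached 0.036, although genes are not independent). It was 1 of 30 such relations computed, and the contrasts within Zn deficiency and within Zn excess correlated with each other at 0.588. The share of clean tags in genes does not account for the count, because 261 genes were still higher with size factors. Whether these genes vary with harvest time, plant state or library making is open, as is a Zn response that varied in strength between the replicates. The library contrast within Zn excess, which uses no Cd exposure library either, also correlated with the Cd exposure change (Spearman's rho -0.345). The calls under Cd exposure are therefore open to the same doubt.

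The 62 genes higher under Zn deficiency and lower under Cd exposure also varied between libraries within conditions. Their median library contrast was 28.2% of their level within Zn excess (central 95% of random lists, -4.75% to 13.7%), -51.0% within the control (-4.61% to 6.25%), 15.7% within Fe deficiency (-8.09% to 5.32%) and 11.1% within Zn deficiency (-16.5% to 6.81%). Within Cd exposure, where the genes were lower than in the control, it was 7.42% and lay inside the random range (1.08% to 10.8%). A set of genes that fluctuates together between replicates, those of the control included, is thus a candidate explanation, and a response to the metal supply stays open beside it.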
